A study of Homo sapiens with 8 samples.

How the data were processed

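SAS cells, an established line from an oral squamous cell carcinoma, were transfected with 10 nM of miR-634 or of a negative control miRNA (miR-NC) and lysed after 24 h, per the labels. RNA bound by AGO2 was recovered by immunoprecipitation (RIP) and set beside the RNA of the lysate (Input). The series has 8 samples, 2 in each combination of transfection and RNA fraction. Of these, 6 arrays were analysed: miR-NC Input replicate 1, miR-NC RIP replicates 1 and 2, miR-634 Input replicates 1 and 2, and miR-634 RIP replicate 2. The other 2 samples, miR-NC Input replicate 2 and miR-634 RIP replicate 1, were not analysed here. The design text describes Input as total RNA, whereas a label of the Input samples names a normal rabbit IgG antibody. The values are described here as Input without settling which applies. Nothing in the labels says that the duplicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

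Each deposited file holds the intensity of every spot on 1 Agilent array, labelled with Cy3 in 1 colour, per the labels' protocols. Per the file headers, the intensities were extracted with Feature Extraction 12.0.1.1 on array design 072363, annotated on genome build hg19. The submitters' processing notes name version 9.1 of the same software. The deposited processed intensity is the background-subtracted and detrended spot signal, on a linear scale and not normalized between arrays, per the file headers. Dim spots carry a small positive surrogate signal there. How the authors normalized between arrays is not given in the sources used here.

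An array holds 62976 spots, of which 60901 were not control spots, and these measured 58201 probes. Control spots and spots marked as outliers were left out (57 to 133 marked spots per array), and spots of one probe were averaged. No spot was saturated. The files give accessions in place of gene names. Of the 58201 probes, 33080 carry RefSeq accessions, and 31014 of these were named by matching the accession without its version to a table of RefSeq genes on the GRCh38.p14 assembly. This named 22375 genes and left 27187 probes unnamed. Because the assembly differs from that of the array design, no coordinates are given. A gene was represented by its probe with the highest mean normalised signal. Over 3205 genes with at least 2 tested probes, the differences from 2 probes correlated across genes with r between 0.517 and 0.764, depending on the comparison.

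The main values are log2 of the processed intensity minus log2 of the array's 75th percentile. A probe was kept if it was well above background on at least 3 arrays. This left 21432 probes, of which 21420 had a value on all 6 arrays and were tested. They represent 13029 named genes. One model with a mean for each of the 4 groups was fitted in limma 3.58.1 (R 4.3.3, lmFit and eBayes without a trend), with Benjamini-Hochberg adjustment over probes and calls at an adjusted p under 0.05. The fit has 2 residual degrees of freedom, from the pairs of miR-NC RIP and miR-634 Input arrays, and a prior with 1.65 degrees of freedom and an SD of 0.0927. The lone miR-NC Input and miR-634 RIP arrays were assumed to vary like these pairs. The 6 comparisons were the enrichment of RIP over Input, averaged and in each transfection, the miR-634 effect in Input and in RIP, and the difference of the enrichments. Every tested value is a limma estimate with its standard error (SE). All Input arrays lie on slide 1 and all RIP arrays on slide 2, with 1 scan each, so slide and RNA fraction cannot be told apart. Each slide holds both transfections, so the comparisons of miR-634 with miR-NC were made within a slide, and an additive slide effect cancels in the difference of the enrichments.

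A gene not well above background on every array of a group has only a bound there. Such folds are given as "at least", from the bright group's mean against the higher of the dim probe's own signal and the lowest signal well above background on each array of the dim group. Gene lists were tested with camera at a preset inter-gene correlation of 0.01 over 1 probe per gene, adjusted over the 26 lists with at least 5 measured genes, in 4 comparisons. Camera was repeated with an estimated correlation, which called 0 lists in each of the 4 comparisons, and fry was run beside it. For histone genes in RIP the estimate was 0.00125, under the preset, yet camera's p went from 2.39e-10 to 0.0171. With an estimated correlation, camera's test rests on the 2 residual degrees of freedom of the fit. A call was hardly attainable there, whatever the correlation. A call lost in this repeat is therefore not by itself a sign of correlation among a list's genes. The repeat cannot decide whether such correlation accounts for a call at the preset. The estimate was 0.507 for ribosomal proteins and 0.219 for interferon response genes. The list of reported miR-634 targets was written from memory of the literature and was not checked against it. BIRC2 may have been chosen on these samples, and its place in that list is then not independent evidence. The 27 gene lists, the model, its alternatives and the rule for named genes were set before the data were examined. That rule took, per comparison, the 10 largest called rises and falls among genes measured on all arrays compared, up to 3 bounds per direction, the 4 members with the smallest p of each list spoken of, and always AGO2, PRKCA (the host gene of miR-634) and the 9 reported targets. NFE2L2, one of these, was not well above background on any array and was not tested.

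On data simulated with the fitted spread over 21420 probes, with variances capped at their 99th percentile, the miR-634 effect in RIP recovered 80% of 50 probes changed 8-fold, 68% of those changed 4-fold and 2% of those changed 2-fold. In Input, 78% were recovered at 8-fold and 50% at 4-fold, which missed a target of 80% set for the largest fold. When only 200 probes changed in RIP, the effect on enrichment recovered 0% at 8-fold, and it recovered 28% when they changed in Input. With 30% of probes changed in RIP, 3.64% of the calls were false. The simulation gave the miR-634 RIP array the spread fitted from the replicate pairs. A one-off difference of that array was not simulated, so this share does not measure false calls from such a difference. Shifting the cholesterol synthesis list by 1 on the log2 scale made camera call that list and no other.

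Alternatives covered the background correction, the scaling, the filter, the variance model, the threshold, the replicate number as a block, the groups in the fit and leaving out arrays. The files hold no mean signal per spot, so the normexp alternative used median signals (offset 50). A block for slide was not run, because slide and fraction coincide. The tests planned on miR-634 seed sites in 3′ UTRs were not run, because no transcript sequences were at hand. Figures were drawn with matplotlib 3.10.9. The number of arrays limits the precision of every value.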

Results

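The series asked which transcripts AGO2, the Argonaute protein that carries miRNAs to their targets, binds in SAS oral squamous carcinoma cells that received miR-634. RNA was measured on 6 arrays: miR-NC Input (n = 1), miR-NC RIP (n = 2), miR-634 Input (n = 2) and miR-634 RIP (n = 1). Between 36.3% and 43.3% of the spots on an array were well above background. The 75th percentile of the signal was 153 to 212 intensity units on the RIP arrays and 296 to 334 on the Input arrays. Over 21420 probes, the miR-NC RIP pair differed with an SD of 0.31 on the log2 scale (r = 0.994) and the miR-634 Input pair with an SD of 0.43 (r = 0.988). The single miR-634 RIP array differed from each miR-NC RIP array with an SD of 1.45 (r = 0.881 and 0.880). Calls rest on limma's adjusted p, and a group with 1 array has no replicate check of its own.

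The first comparison set AGO2-bound RNA against Input, averaged over both transfections. The long non-coding RNA LINC01160 had the highest called enrichment among genes measured on all arrays, at 6.13 ± 0.09 (SE) on the log2 scale, or 70.0-fold. It was followed by LINC01352 (5.56 ± 0.16), KRTAP10-8 (5.50 ± 0.09), NUDT10 (5.11 ± 0.08) and SEMA7A (5.01 ± 0.13). IGF2, a growth factor, MYLIP, a ubiquitin ligase, PTPMT1, GARS1-DT and NRAS, a RAS GTPase, rose by between 3.93 and 4.66. DNAH14, at -2.75 ± 0.06, and TWF1, which binds actin monomers, at -2.67 ± 0.06, were the most depleted of the genes measured on all arrays. LACTB2, SEC63 of the endoplasmic reticulum translocation machinery, the DNA polymerase gene POLK, CFAP36, RPL29P2, PPP1R2, ZFAND1 and NSA2 lay between -2.56 and -2.34. PTGER3 was at least 34.9-fold, PRR23B at least 12.9-fold and ASCL5 at least 11.4-fold higher in RIP, where Input was not well above background. In the other direction, SNORD1B was at least 3.70-fold, DEPDC1-AS1 at least 2.21-fold and SAMD3 at least 2.15-fold higher in Input.

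Targets of let-7, an abundant miRNA family, were enriched as a list: 21 of 30 measured genes rose and 4 fell, with a median of 0.92 (camera adjusted p = 0.0161; adjusted p = 0.622 with an estimated correlation). The same number, 25, was called adjusted over the list alone. Besides NRAS (3.93 ± 0.06), ACVR1C rose by 2.52 ± 0.10, the nuclear receptor gene NR6A1 by 2.51 ± 0.08 and CDC34, a ubiquitin-conjugating enzyme, by 1.81 ± 0.06. Replication-dependent histone genes, whose transcripts end without a poly(A) tail, were depleted: 38 of 52 fell and 7 rose, with a median of -0.55 (camera adjusted p = 0.00329; adjusted p = 0.622 with an estimated correlation), and 46 were called adjusted over the list alone. Their values included -1.03 ± 0.05 for H2BC5 and -0.87 ± 0.06 for H4C6. This came from the miR-634 cells, where 43 fell and 5 rose (median -1.34), while in miR-NC cells 1 fell and 8 rose (median 0.14). Near-identical histone genes can share probe signal. Of 22 cholesterol synthesis genes, 16 rose and 3 fell, with a median of 0.85 (camera adjusted p = 0.0463; adjusted p = 0.622 with an estimated correlation), and 20 were called adjusted over the list alone. STARD4, a sterol carrier, rose by 2.10 ± 0.09 and INSIG1, a sterol sensor, by 1.48 ± 0.05, whereas the isomerase gene IDI1 fell by 1.55 ± 0.06. Here too the median lay at 1.85 in miR-634 cells, with 17 genes higher and 3 lower, and at -0.088 in miR-NC cells, with 5 higher and 5 lower. The let-7 targets had medians of 1.30 (20 higher, 5 lower) in miR-634 and 0.32 (13 higher, 4 lower) in miR-NC cells. The camera call of the cholesterol synthesis list ended under 9 alternatives besides the estimated correlation (adjusted p = 0.0509 to 0.306), among them leaving out miR-634 Input replicate 1 (adjusted p = 0.0584) or 2 (adjusted p = 0.0583) or miR-NC RIP replicate 2 (adjusted p = 0.0509), and the let-7 call ended without a filter on dim probes (adjusted p = 0.0617).

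Averaged over both transfections, limma called 15943 of 21420 probes, 8055 higher and 7888 lower in RIP. The higher share was 50.5%, and it was 37.4% with arrays centred on their medians. In miR-NC cells 7754 probes were called (3430 higher, 4324 lower), and in miR-634 cells 16782 (8340 higher, 8442 lower). The log2 enrichments had an SD over probes of 0.74 in miR-NC and of 1.72 in miR-634 cells. Across 13029 genes, which are not independent replicates, both enrichments correlated with Pearson's r = 0.331 and Spearman's rho = 0.364, and they share no array. Of the genes, 1356 were higher in both, against 879 for independent lists, and 1889 were lower in both, against 1186. AGO2's own transcript was called in miR-NC cells (0.54 ± 0.11) and not in miR-634 cells (-0.19 ± 0.11, limma adjusted p = 0.206), and the miR-NC call ended without any 1 of the 4 arrays that could be left out (limma adjusted p up to 0.0975). Slide and fraction cannot be told apart in these enrichments. The miR-NC calls fell to 4377 (2436 higher, 1941 lower) and 4380 (2437 higher, 1943 lower) without miR-634 Input replicate 1 or 2, so that the balance of directions turned, and without either miR-NC RIP array limma called 0, with 9745 (without replicate 1) and 9588 (without replicate 2) probes at an unadjusted p under 0.05.

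The second comparison asked how miR-634 changed the RNA in Input. Genes of the integrated stress response were higher in miR-634 cells: 16 of 25 rose and 2 fell, with a median of 0.68 (camera adjusted p = 2.69e-05; adjusted p = 0.276 with an estimated correlation), and 20 were called adjusted over the list alone. CHAC1, which degrades glutathione, rose by 2.80 ± 0.14, DDIT3, encoding the transcription factor CHOP, by 2.58 ± 0.16, the asparagine synthetase gene ASNS by 2.05 ± 0.09 and CEBPB by 1.36 ± 0.08. Cholesterol synthesis genes were lower: 17 of 22 fell and 1 rose, with a median of -0.94 (camera adjusted p = 9.81e-06; adjusted p = 0.276 with an estimated correlation), and 20 were called adjusted over the list alone. SREBF2, a transcriptional regulator of the pathway, fell by 1.15 ± 0.08. Histone genes fell in 28 of 52 cases and rose in 1 (median -0.49, camera adjusted p = 9.81e-06; adjusted p = 0.276 with an estimated correlation), with 39 called adjusted over the list alone, among them H1-3 (-1.50 ± 0.10) and H2BC3 (-0.98 ± 0.08).

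Several mitochondrial and metabolic lists were lower in miR-634 Input. Nuclear-encoded genes of oxidative phosphorylation fell in 20 of 65 cases and rose in 0 (median -0.25, camera adjusted p = 0.00120; adjusted p = 0.276 with an estimated correlation), the same number as adjusted over the list alone. The ATP synthase subunit genes ATP5F1B, ATP5MG and ATP5MC3 fell by 1.53 ± 0.12, 1.03 ± 0.09 and 0.97 ± 0.09. Of 27 genes of mitochondrial dynamics and biogenesis, 14 fell and 1 rose (median -0.41, camera adjusted p = 0.0280; adjusted p = 0.482 with an estimated correlation), with 16 called adjusted over the list alone. They included the kinase gene PINK1 (-1.45 ± 0.08) and DNM1L (-1.30 ± 0.09), which drives mitochondrial fission, and GABPA rose by 1.31 ± 0.08. Glycolysis genes fell in 8 of 19 cases and rose in 0 (median -0.40, camera adjusted p = 0.0355; adjusted p = 0.482 with an estimated correlation), with 12 called adjusted over the list alone, and the glucose transporter gene SLC2A1 was at -1.11 ± 0.10. These 3 list calls ended under each of the 3 other scalings, with medians that stayed negative (highest adjusted p = 0.178, for glycolysis).

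Interferon response genes fell in 13 of 27 cases and rose in 1 (median -0.50, camera adjusted p = 0.0258; adjusted p = 0.532 with an estimated correlation), with 18 called adjusted over the list alone, among them IFIT1 (-1.96 ± 0.11), STAT2 (-1.25 ± 0.08) and ISG15 (-1.11 ± 0.08). Squamous keratinocyte genes rose in 8 of 29 cases and fell in 2 (median 0.43, camera adjusted p = 0.00646; adjusted p = 0.301 with an estimated correlation), with 12 called adjusted over the list alone. The cornified envelope gene SPRR1B rose by 2.37 ± 0.12 and the keratin gene KRT6A by 1.32 ± 0.10, while S100A9 fell by 1.51 ± 0.16. Nuclear non-coding RNAs rose in 11 of 24 cases and fell in 2 (median 0.42, camera adjusted p = 0.0139; adjusted p = 0.482 with an estimated correlation), with 16 called adjusted over the list alone. SCARNA2, a small RNA of Cajal bodies, rose by 3.93 ± 0.09 and DANCR fell by 1.37 ± 0.10. The interferon call ended with probes well above background on every array (adjusted p = 0.0526), the squamous call without a filter (adjusted p = 0.109), and the nuclear RNA call with normexp (adjusted p = 0.0728) and without a filter (adjusted p = 0.164). Of 9 measured leukocyte markers, CSF1R (-2.43 ± 0.09) and CD14 (-1.67 ± 0.10) fell, 7 did not pass, and the list was not called (median -0.48, camera adjusted p = 0.239).

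Beyond the lists, and among genes well above background on all Input arrays, the largest called rises in Input after SCARNA2 were those of NUPR1, a stress-induced chromatin protein, at 3.87 ± 0.08, SNORD46 (3.72 ± 0.17) and LURAP1L-AS1 (3.62 ± 0.10). MSANTD3-TMEFF1, the transcription factor gene DLX2, PHF21B, the cytokine gene IL11 and the retinol carrier gene RBP4 rose by between 2.91 and 3.56. LINC01213 (-3.96 ± 0.13), LIMCH1 (-3.65 ± 0.11), TMT1A (-3.44 ± 0.18) and the aldo-keto reductase gene AKR1B10 (-3.01 ± 0.17) fell most among these genes. ANXA9, LAPTM5, ELAPOR1, RPIA, LY6E-DT and CAVIN2 were between -2.91 and -2.60. SLC28A2 was at least 49.7-fold, the desmosomal cadherin gene DSG2 at least 26.2-fold and LINC01038 at least 13.2-fold higher in miR-634 Input. MAN1B1-DT was at least 69.2-fold, MAPRE3 at least 14.3-fold and MS4A4A at least 8.87-fold higher in miR-NC Input. Both sets of bounds rest on the single miR-NC Input array, where no replicate could check a signal. SLC28A2, DSG2 and LINC01038 were also well above background on a RIP array, since a kept probe needed at least 3 arrays. For them, a low reading of that 1 Input array alone is not excluded. AGO2 rose by 0.71 ± 0.11 and PRKCA, the host gene of miR-634, by 0.49 ± 0.09. In all, limma called 6571 of 21420 probes, 2657 higher and 3914 lower, and the higher share was 40.4%, against 27.1% with arrays centred on their medians. The count was 2822 without miR-634 Input replicate 1 and 2637 without replicate 2. Leaving out 1 array ended the calls of AGO2 (limma adjusted p up to 0.0853), PRKCA (up to 0.116) and MSANTD3-TMEFF1 (up to 0.0879).

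The third comparison set the RNA that co-precipitated with AGO2 in miR-634 cells against that in miR-NC cells, within slide 2. Genes of glutamine metabolism and amino acid transport were higher in the miR-634 RIP: 18 of 21 rose and 2 fell, with a median of 1.81 (camera adjusted p = 0.00101; adjusted p = 0.632 with an estimated correlation), and 20 were called adjusted over the list alone. The glutamine transporter gene SLC1A5 rose by 3.92 ± 0.10, the transaminase genes GOT1 and GPT2 by 3.83 ± 0.09 and 2.90 ± 0.08, and GFPT1, which uses glutamine to make hexosamines, by 3.28 ± 0.10. Integrated stress response genes rose in 17 of 25 cases and fell in 6 (median 1.23, camera adjusted p = 0.0321; adjusted p = 0.632 with an estimated correlation), with 23 called adjusted over the list alone. ALDH1L2 rose by 4.11 ± 0.13, SESN2 by 3.98 ± 0.09, HERPUD1 by 3.27 ± 0.09 and TRIB3 by 2.90 ± 0.08. That list's call ended with quantile normalization (adjusted p = 0.0682), with quantile normalization within each fraction (adjusted p = 0.0694) and with both other filters (adjusted p = 0.0621 and 0.122). The integrated stress response list also rose in Input (median 0.68). Camera did not call it for the difference of the enrichments (median 0.62, 13 higher, 8 lower, camera adjusted p = 0.391).

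Histone transcripts were lower in the miR-634 RIP: 47 of 52 fell and 2 rose, with a median of -1.82 (camera adjusted p = 6.23e-09; adjusted p = 0.445 with an estimated correlation), and 50 were called adjusted over the list alone. H2BC3 fell by 2.86 ± 0.08 and H2BC9 by 2.78 ± 0.09. Ribosomal protein genes fell in 43 of 74 cases and rose in 12 (median -0.89, camera adjusted p = 0.00685; adjusted p = 0.785 with an estimated correlation), with 56 called adjusted over the list alone. RPL36 fell by 3.23 ± 0.12 and RPL29 by 3.04 ± 0.08, while RPS16 rose by 2.05 ± 0.08. Among genes well above background on all RIP arrays, the elastase inhibitor gene PI3 had the largest called rise, 5.39 ± 0.13, followed by LINC00673 (5.20 ± 0.08), ZBTB11-AS1 (5.18 ± 0.11), PGBD3 (4.98 ± 0.13) and the growth factor gene BMP2 (4.83 ± 0.13). FAM241B, FARS2, HOXC13-AS, CRYZ and C3orf33 rose by between 4.55 and 4.68. The mitochondrial ribosomal protein gene MRPS17 (-5.38 ± 0.18), LYRM1 (-5.23 ± 0.08) and MRPS14 (-4.32 ± 0.09) fell most among them. CAVIN2, ZNF226, RBIS, the RNA-binding protein gene YBX1, THAP1, IFIT1 and SCEL were between -4.13 and -3.77. Some of the rises went with higher Input signal in miR-634 than in miR-NC cells. Mean Input signals were 1.61 against -0.76 for PI3, 3.34 against 1.59 for LINC00673 and 2.57 against 0.94 for BMP2. Those of ZBTB11-AS1, PGBD3 and FAM241B were higher too, and those of FARS2, HOXC13-AS, CRYZ and C3orf33 were lower.

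ARSJ was at least 32.3-fold, MYPN at least 20.6-fold and TIGD3 at least 18.4-fold higher in the miR-634 RIP, and ZNF613, ANXA9 and UNC5B-AS1 were at least 13.1-fold, 11.9-fold and 10.9-fold higher in the miR-NC RIP. PRKCA fell by 1.63 ± 0.09, and AGO2 was at -0.01 ± 0.11 (limma adjusted p = 0.942). In all, limma called 15415 of 21420 probes, 7236 higher and 8179 lower in the miR-634 RIP. The miR-634 RIP group has 1 array, so its own spread was not measured.

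The fourth comparison, which the design names as its outcome, was the difference of the enrichments, miR-634 minus miR-NC. All 8 measured genes of the reported miR-634 targets had a higher enrichment in miR-634 cells, with a median of 2.24 (camera adjusted p = 0.00270; adjusted p = 0.465 with an estimated correlation), and 8 were called adjusted over the list alone. SLC1A5 rose by 4.52 ± 0.14, or 23.0-fold, APIP, which inhibits apoptosome formation, by 3.79 ± 0.19, and BIRC2, an inhibitor of apoptosis that may have been chosen on these samples, by 3.27 ± 0.13. The mitochondrial transcription factor gene TFAM rose by 2.35 ± 0.11, the lysosomal membrane gene LAMP2 by 2.13 ± 0.11, OPA1, which fuses inner mitochondrial membranes, by 2.03 ± 0.16, BIRC5 by 1.85 ± 0.12 and XIAP by 0.66 ± 0.15. In RIP alone, all 8 rose (median 1.30, camera adjusted p = 0.00685; adjusted p = 0.632 with an estimated correlation), and 8 were called adjusted over the list alone. In Input alone, 7 of the 8 fell (median -0.81, camera adjusted p = 0.00255; adjusted p = 0.301 with an estimated correlation), and 7 were called adjusted over the list alone. The Input falls ran from -1.30 ± 0.13 for APIP and -1.29 ± 0.11 for OPA1 to -0.44 ± 0.09 for BIRC2, and XIAP, at -0.23 ± 0.10, did not pass (limma adjusted p = 0.176). In the difference of the enrichments and in RIP, 1 of 2 OPA1 probes differed in sign from the other, and 2 of 3 LAMP2 probes had the sign given. In Input all probes of both genes had the same sign. Leaving out 1 array ended the Input calls of BIRC2 (limma adjusted p up to 0.146), SLC1A5 (up to 0.0968) and LAMP2 (up to 0.0661), and the calls of XIAP in RIP (up to 0.0628) and in the difference of the enrichments (up to 0.0699). Centring arrays on their medians also ended the Input calls of BIRC5, BIRC2, LAMP2 and SLC1A5 and the RIP calls of BIRC5, OPA1 and XIAP. That setting scales on background, since the array medians (8.44 to 14.8 intensity units) lay below the lowest signals well above background (22.1 to 38.2).

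**Figure D1:**
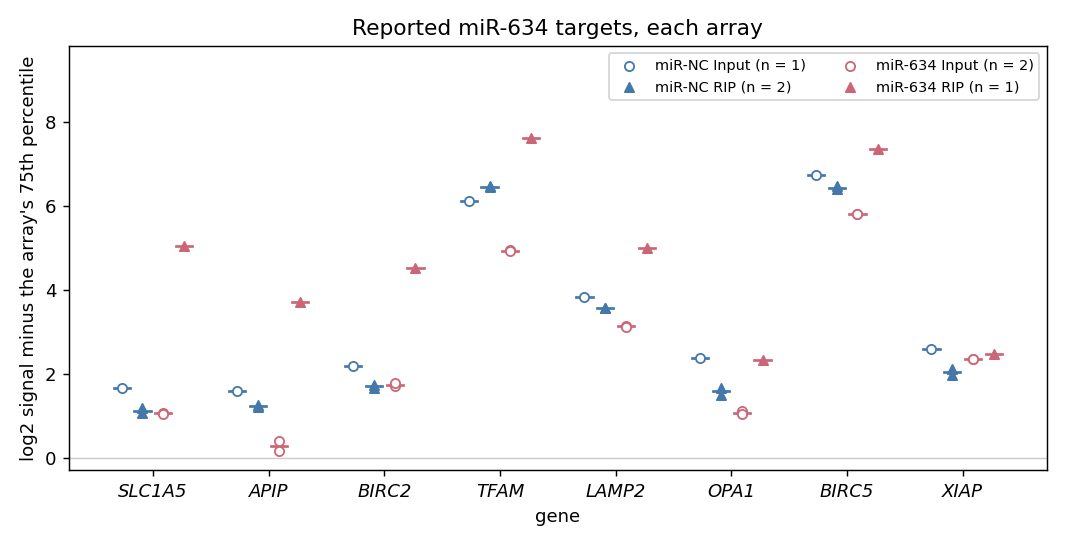
Normalised signal (log2 minus the array's 75th percentile) of the 8 measured reported miR-634 targets on each of the 6 arrays, with circles for Input, triangles for RIP and short lines at group means. The miR-634 RIP array lies above both miR-NC RIP arrays for all 8 genes, and above their mean by 3.92 for SLC1A5 and by 0.43 for XIAP.

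Other lists also differed in enrichment between the transfections. Genes of glutamine metabolism and amino acid transport had a higher enrichment in miR-634 cells in 17 of 21 cases and a lower one in 2 (median 1.71, camera adjusted p = 0.00190; adjusted p = 0.465 with an estimated correlation), with 19 called adjusted over the list alone. They included GOT1 (4.34 ± 0.12), GFPT1 (3.76 ± 0.15) and SLC38A5 (3.64 ± 0.12). Cholesterol synthesis genes rose in 16 of 22 cases and fell in 3 (median 1.63, camera adjusted p = 0.00857, and 0.465 with an estimated correlation), with 19 called adjusted over the list alone. Among them were PMVK (4.39 ± 0.20), STARD4 (3.87 ± 0.18) and FDPS (3.09 ± 0.13). In RIP alone camera did not call the cholesterol synthesis list (median 0.58, 12 higher, 6 lower), and in Input its median was -0.94. Histone genes fell in 45 of 52 cases and rose in 3 (median -1.41, camera adjusted p = 1.37e-06; adjusted p = 0.465 with an estimated correlation), with 48 called adjusted over the list alone. Ribosomal protein genes fell in 34 of 74 cases and rose in 12 (median -0.81, camera adjusted p = 0.0150; adjusted p = 0.958 with an estimated correlation), with 44 called adjusted over the list alone. That last call ended without miR-NC RIP replicate 1 (adjusted p = 0.0502).

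**Figure D2:**
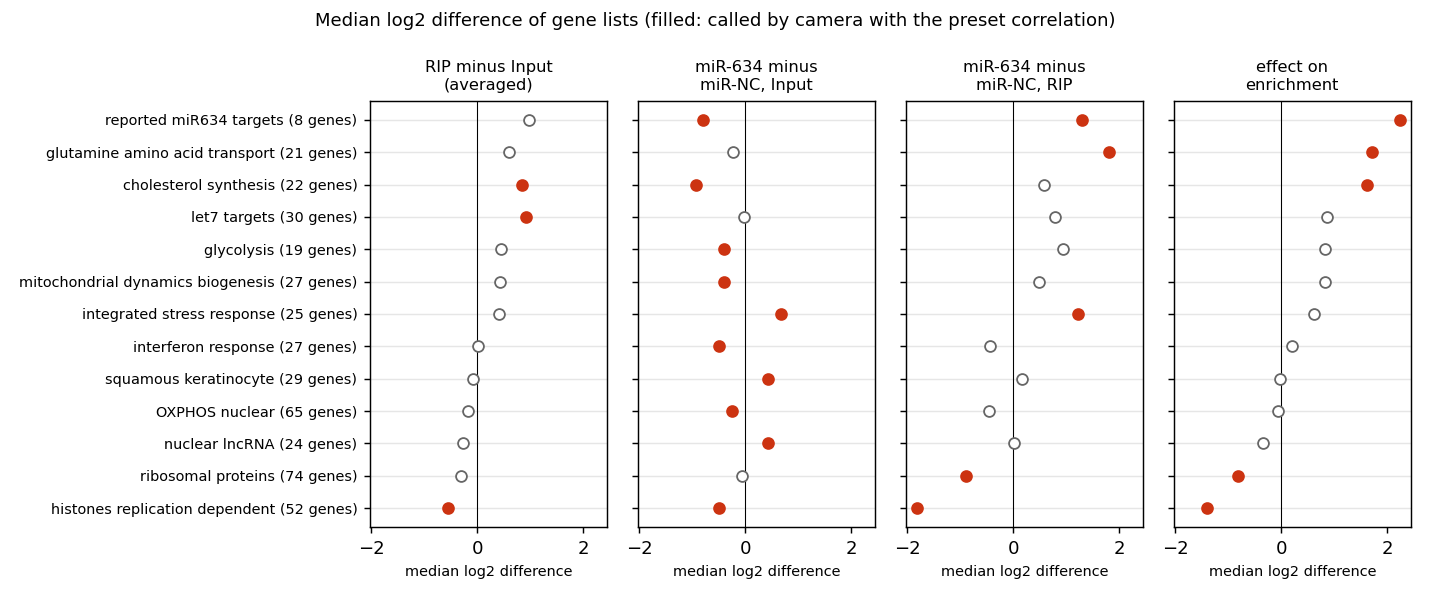
Median log2 difference over the measured genes of 13 gene lists in 4 comparisons, with filled points where camera called the list at the preset correlation. The reported miR-634 targets lie at -0.81 in Input and at 1.30 in RIP, and the histone genes at -0.49 and -1.82.

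Among genes well above background on all arrays, the oxidoreductase gene CRYZ (5.70 ± 0.14), UFC1, a ufmylation enzyme (5.63 ± 0.11), and ATP6V0B, a proton pump subunit (5.57 ± 0.16), gained the most enrichment. HOXC13-AS, FARS2, TMEM45A, TMEM18, MFSD1, SDF2 and NUDT16L1 gained between 5.01 and 5.40. LYRM1 (-5.67 ± 0.11), MRPS17 (-5.22 ± 0.26), THAP1 (-5.12 ± 0.12) and the excision repair gene ERCC5 (-4.99 ± 0.12) lost the most among these genes, and LZTFL1, YBX1, TOE1, ZNF226, MRPS14 and H3C1 were between -4.82 and -4.42. PRKCA was at -2.12 ± 0.12 and AGO2 at -0.72 ± 0.16. The AGO2 call ended without miR-634 Input replicate 2 (limma adjusted p = 0.0642, log2 -0.66) and without miR-NC RIP replicate 2 (limma adjusted p = 0.0551, log2 -0.66). In all, limma called 14001 of 21420 probes, 6706 higher and 7295 lower.

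The changes in Input and in RIP, which share no array, were set against each other across genes. They correlated with Pearson's r = -0.0404 and Spearman's rho = -0.122 over 13029 genes. Of these, 1546 were lower in miR-634 Input and higher in the miR-634 RIP, against 1017 for independent lists. The opposite combination held 767 genes, against 726, and 703 were higher in both, against 712. Another 777 genes were lower in both, against 1038. The correlation was -0.251 over the 2606 brightest genes and 0.209 over the 2606 dimmest.

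**Figure D3:**
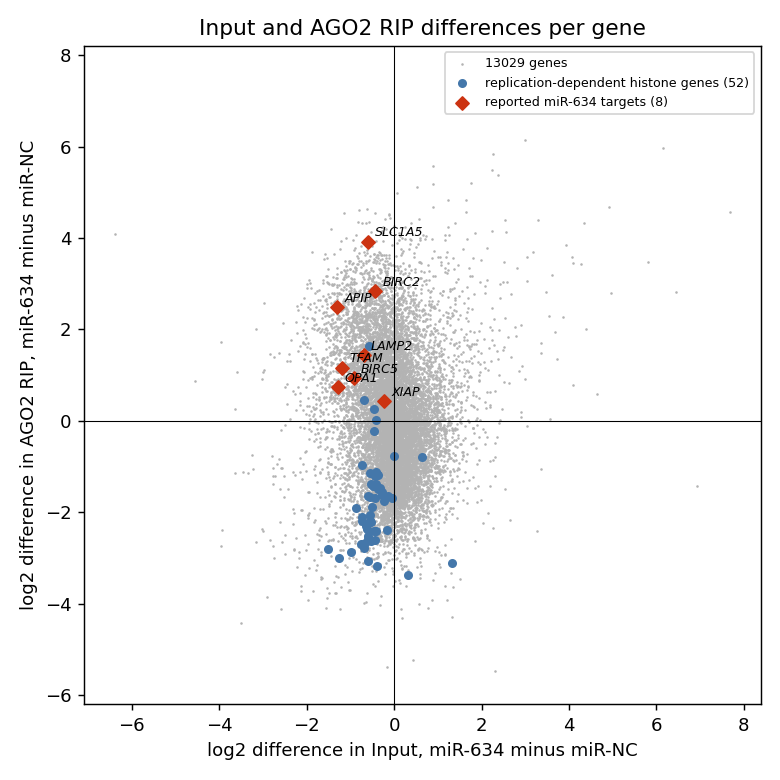
Log2 difference of miR-634 minus miR-NC in Input (horizontal) and in AGO2 RIP (vertical) for 13029 genes (grey), with the 8 reported miR-634 targets (diamonds) and 52 histone genes (blue) marked. All 8 targets lie above 0 in RIP and below 0 in Input, where XIAP did not pass the test; differences of genes near background are less certain.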

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

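In this part, the tests on the miR-634 RIP array and on small nuclear and nucleolar RNAs were chosen after the result was seen, and the test on DNA replication genes before.

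The enrichment by AGO2 differed between the transfections by limma's test of that difference, for 14001 of 21420 probes. By list, the median log2 difference (miR-634 minus miR-NC) was 2.24 for the reported miR-634 targets, 1.71 for glutamine metabolism and amino acid transport, 1.63 for cholesterol synthesis, -0.81 for ribosomal proteins and -1.41 for histones. Of the reported targets, SLC1A5 was at 4.52, APIP at 3.79, BIRC2 at 3.27, TFAM at 2.35, LAMP2 at 2.13, OPA1 at 2.03, BIRC5 at 1.85 and XIAP at 0.66. AGO2 itself was at -0.72 and PRKCA at -2.12. Among genes well above background on all arrays, the 10 with the highest called values were CRYZ (5.70), UFC1 (5.63), ATP6V0B (5.57), HOXC13-AS (5.40), FARS2 (5.26), TMEM45A (5.22), TMEM18 (5.17), MFSD1 (5.15), SDF2 (5.11) and NUDT16L1 (5.01). The 10 of these genes with the lowest were LYRM1 (-5.67), MRPS17 (-5.22), THAP1 (-5.12), ERCC5 (-4.99), LZTFL1 (-4.82), YBX1 (-4.79), TOE1 (-4.65), ZNF226 (-4.58), MRPS14 (-4.50) and H3C1 (-4.42).

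These differences rest largely on the miR-634 RIP array, which differed from each miR-NC RIP array with an SD of 1.45, against 0.31 within the miR-NC RIP pair. The cholesterol synthesis difference also rests on a fall in Input (median -0.94, against 0.58 in RIP). A lower RNA yield than on the miR-NC RIP arrays is argued against by spike-in signal, which relative to the 75th percentile was 0.846 times theirs. On the RIP arrays that ratio averaged 3.43 times that of the Input arrays. Noise of dim genes is argued against by an SD of 1.40 over the 2606 brightest genes (0.15 within the miR-NC RIP pair there), and artefacts of single probes by r = 0.749 between 2 probes of one gene. AGO2 binding to miR-634 targets may account for a part: the reported targets' median in RIP lay at the 98.0th percentile of 10000 random lists matched on signal. Without BIRC2 it lay at the 95th, and the median of 1.16 was within the central range of random lists (-1.27 to 1.44). For the difference of the enrichments, the targets' median lay at percentile 99.75. Without BIRC2 that percentile was 99.25 (median 2.13, random lists -1.30 to 1.75). This difference includes the targets' falls in Input, where the percentile was 0.14, and 0.09 without BIRC2. Among genes called in both fractions, 68.7% of those higher in RIP were lower in Input, against 50.3% of those lower in RIP, a difference of 18.4 percentage points. Of all 4595 genes called in Input, 2703 were lower. These genes were not selected as miR-634 targets, since the tests on seed sites were not run, so the shares do not decide whether targets were bound. With 1 miR-634 RIP array, an effect of miR-634 and a one-off difference of this single immunoprecipitation cannot be told apart.

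Histone transcripts were lower in the miR-634 RIP (median -1.82) and, less so, in miR-634 Input (-0.49). Whether fewer S-phase cells could account for the fall in Input stays open, since the median of 20 DNA replication genes there was -0.14 (SE 0.13). A loss of RNA without poly(A) tails in general may contribute in RIP, where snRNAs (-2.08) and snoRNAs (-0.64) also had medians below 0. Protein-coding genes as a class had a median of 0.0062 there (4597 higher, 4465 lower), although the ribosomal protein genes among them fell (-0.89, 43 of 74 lower), so this explanation stays open. Near-identical histone genes can share probe signal, so the list's 52 genes are fewer independent measurements.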

How the results depend on the processing

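In this part, the count of differences beyond those between replicate arrays was chosen after the result was seen.

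Over 14 alternatives, the 215 gene results kept direction and side of the threshold in 2708 comparisons, fell below it in 190, passed it newly in 13 and reversed in 5. The 23 list results kept both in 270, fell below the threshold in 52 and reversed in 0. Of these 52, 23 came from the estimated correlation, where a call was hardly attainable on 2 residual degrees of freedom. Normexp called 5 lists for the averaged enrichment. Median centring, which scales arrays on spots not well above background, called 2786 probes for enrichment in miR-NC and 2699 for the miR-634 effect in Input. It moved the median of all probes by -0.26 in the averaged enrichment, by -0.13 in Input and by -0.19 in RIP. Quantile normalization, between arrays or within each fraction, moved it by -0.13 in RIP and in the effect on enrichment. Without a filter, 35384 probes were called for the averaged enrichment, 23841 in miR-NC, 30598 in miR-634, 23038 for Input and 33312 for RIP, and the higher share rose from 50.5% to 77.2% in the averaged enrichment, from 49.7% to 73.9% in miR-634, from 40.4% to 80.0% for Input, from 46.9% to 76.7% for RIP and from 47.9% to 58.8% for the effect on enrichment. With a 2-fold minimum the counts were 7231 for the averaged enrichment, 2125 in miR-NC, 2308 for Input and 10080 for RIP. Differences beyond the 99th percentile of those within replicate pairs (1.44) numbered 1037 in miR-NC, 9189 in miR-634, 1112 for Input and 6820 for RIP. The replicate block gave 3782 in miR-NC and 3379 for Input. Pairing was untestable, as the correlation (0.0910) spans both transfections. A fit of only the 2 groups contrasted gave 4380 in miR-NC. The higher share of the miR-NC calls, 44.2% with the settings of the report, passed 50% with quantile normalization within each fraction (53.2%), the block (54.5%), only the 2 groups contrasted (55.6%), a 2-fold minimum (71.0%), no filter (81.7%) and differences beyond replicate pairs (86.3%). Other comparisons crossed 50% as well, besides those without a filter. In miR-634 the share was 52.0% with normexp, 52.6% with probes well above background on every array, 50.7% with a 2-fold minimum, 52.3% beyond replicate pairs and 50.3% without miR-634 Input replicate 1. In RIP it was 50.9% with normexp, 50.5% with that filter and 51.0% beyond replicate pairs, and in the effect on enrichment 52.2% with normexp, 50.5% with that filter and 50.3% with a 2-fold minimum. In the averaged enrichment it was 47.1% with quantile normalization, 49.9% with it within each fraction and 37.4% with median centring, and 7615 probes were called in each direction without miR-NC RIP replicate 2. With an estimated correlation, camera called 0 lists in each of the 4 comparisons (lowest adjusted p = 0.276), while fry called 25, 19, 23 and 19 for the averaged enrichment, Input, RIP and the effect on enrichment.

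Leaving out 1 array gave 15175 to 15276 calls for the averaged enrichment, 0 to 4380 in miR-NC, 15869 to 16570 in miR-634, 2637 to 4446 for Input, 14260 to 15103 for RIP and 12882 to 13216 for the effect on enrichment. The lists called were 2 to 4, 10 to 11, 5 and 4 to 5 for the averaged enrichment, Input, RIP and the effect on enrichment. Reversals were those of XIAP in the miR-634 enrichment (-0.069 with quantile normalization, -0.17 with median centring), of AGO2 (-0.083) and OPA1 (-0.028) in the averaged enrichment with median centring, and of AGO2 in RIP, at 0.058 without miR-NC RIP replicate 2 (-0.01 with all arrays, -0.079 without replicate 1). The cause was not tested for any of these changes except the one for Input without a filter. The lone miR-NC Input and miR-634 RIP arrays could not be left out, since their comparisons then have no value, and each left-out pair leaves 1 array assumed to vary like the remaining pair. A block for slide and the tests of seed sites were not run. Signal over background limits the genes measured, since 36.3% to 43.3% of spots were well above it.

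Without a filter, 18429 of the 23038 probes called for Input were higher in miR-634. The 30300 probes well above background on no array had a median of 0.77 in Input, and 87.1% of them were higher. The shift computed from the arrays' lowest signals and 75th percentiles was 0.78. The background floor of the arrays may account for these calls. No biological explanation was tested.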

Other observations

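In this part, the values by RNA class and the test on targets of endogenous miRNAs were chosen after the result was seen, and the splits of the arrays before.

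Small nuclear and nucleolar RNAs were depleted from the AGO2 precipitates. Of 14 snRNAs, which serve in splicing, 13 were lower in RIP than in Input over both transfections and 0 were higher, with a median of -1.67 (-0.59 in miR-NC and -2.80 in miR-634 cells). Of 176 snoRNAs, which guide RNA modification, 133 were lower and 8 higher, with a median of -0.93 (-0.44 in miR-NC and -1.51 in miR-634 cells). Protein-coding genes had a median of 0.04 (4800 higher and 4447 lower of 11806). In Input, 61 snoRNAs were higher and 36 lower in miR-634 cells, with a median of 0.35.

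Several lists not called by camera held genes that changed in miR-634 Input, where 4595 of all 13029 genes were called. Among 24 targets of p53, 9 rose and 6 fell (median 0.12, camera adjusted p = 0.264), with 16 called adjusted over the list alone: BTG2 rose by 1.96 ± 0.10 and the cell cycle inhibitor gene CDKN1A by 1.90 ± 0.12, and DDB2 was at -1.10 ± 0.08. Of 23 immediate early and stress genes, 11 fell and 3 rose (median -0.28, camera adjusted p = 0.0958), with 14 called adjusted over the list alone, among them CCN2 (-1.66 ± 0.11), FOS (-1.63 ± 0.11) and JUN (-1.34 ± 0.08). Of 25 antioxidant genes regulated by NRF2, 8 fell and 2 rose (median -0.22, camera adjusted p = 0.239), with 12 called adjusted over the list alone, including CBR3 (-1.80 ± 0.09) and AKR1B10 (-3.01 ± 0.17). Among 39 secretory and membrane genes, 10 rose and 11 fell (median 0.13, camera adjusted p = 0.264), with 22 called adjusted over the list alone: the receptor gene MET rose by 1.60 ± 0.08 and the cadherin gene CDH1 was at -2.32 ± 0.09. Of 30 let-7 targets, 6 rose and 10 fell (median -0.02, camera adjusted p = 0.874), with 17 called adjusted over the list alone, and HMGA2 rose by 2.86 ± 0.12 while IGF2BP3 was at -1.85 ± 0.09.

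One hypothesis was that miR-634 displaces endogenous miRNAs from AGO2, which would lower the enrichment of their targets. The median effect on enrichment over 71 measured targets of let-7, the miR-17 family and miR-21 was 0.33 (SE 0.25), with median enrichments of 0.35 in miR-NC and 1.09 in miR-634 cells. By list, none of which camera called, the median was 0.86 for let-7 (19 higher, 10 lower, camera adjusted p = 0.297), 0.42 for miR-21 targets (10 higher, 8 lower, adjusted p = 0.838) and -0.26 for those of the miR-17 family (6 higher, 12 lower, adjusted p = 0.391). The criterion first written took a positive median as against displacement, which this median met. It was made stricter after the result was seen, asking for a median beyond its SE and every list on the same side. The miR-17 family list did not meet the stricter rule. With members going both ways and 1 miR-634 RIP array, displacement stays open.

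The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The split into RIP and Input, which is also the split by slide, called 369 probes in limma, and 1 of the 10 splits, the real one, called as many. The highest of the others, the split by transfection, called 10.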
